A study of Mus musculus with 4 samples.

How the data were processed

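Total RNA of cultured ESC-FC1801 cells and of allograft tumours was extracted with Trizol and a column kit, and libraries followed an Illumina protocol, per the labels' protocols. The submitters' processing notes name CASAVA, TopHat 1.2.0, Cufflinks 1.0.2 and Cuffdiff and the mouse build mm9. Whether the libraries kept strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. There were 2 deposited gene tables of 35604 rows each, 1 for culture and 1 for tumours. Each holds the level of an untreated and a treated library in FPKM, a level scaled to transcript length and to the mapped fragments of the library, as deposited by the authors, with Ensembl gene IDs, symbols and loci. Per the file headers, the authors also deposited the natural log of the fold change, a test statistic and a q-value for each gene, both used here as scores of the authors' own comparison, and a call of significance. All called genes had a q under 0.05, and uncalled q-values reached 2.05, above the range of a probability. The deposited fold was the ratio of the deposited levels (largest difference 1.23e-05 in natural log), and the statistic had the sign opposite to the fold in 100% of the rows where both were finite. A test on the reads of 2 libraries compares those libraries, not the conditions.

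Groups came from the treatment labels. The labels call all 4 samples cultured cells in their sample type, but titles, sources and treatments put 2 of them in tumours, and those were followed. The tables were made separately, so levels were compared only within a table, and only differences were set side by side between them.

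Rows with status FAIL (705 in culture, 347 in tumours) were at 0 in both libraries and were left out with LOWDATA rows (61 and 449), since a 0 there is a failed estimate and not an absent transcript. Genes at 1 FPKM or more in either library were compared, 12676 in culture and 15550 in tumours. The difference was log2(FPKM + 1) of the treated minus that of the untreated library, and genes past 2-fold on that scale were counted per direction. No test was run, since each group has 1 library. Of the compared genes, 249 in culture and 323 in tumours were listed at 0 in the untreated library and 381 and 343 in the treated one, and no ratio is printed for such a gene.

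The 38 gene lists (pathways, complexes and markers of cell types a tumour piece can hold), the rule for named genes and the main alternatives were set before the data were examined. A list's median over its measured members was placed as a percentile among 10000 random lists of the same size, matched on mean level in 20 bins with seed 7, and a list stood apart below 2.5 or above 97.5. The percentile describes these libraries and is not a p-value. In culture 23 lists had 5 or more measured members, of which 5 stood above and 5 below, where chance would put 1.15 outside. In tumours 33 lists did, with 5 above, 9 below and 1.65 by chance. The chance numbers treat list members as independent genes and would be larger if members vary together. Named genes were the 12 higher and 12 lower per comparison with the largest difference among genes the authors' table calls, up to 4 members with the largest difference from each list, every measured heat shock and HSP90 gene, Nf2, and the 10 genes with the largest shared and the 10 with the largest opposite difference. Some genes that meet this rule are not reported here, though they count in their lists. Blank, repeated, predicted, clone and small RNA symbols were left out of these rankings. Symbols in more than 1 row (346) entered lists with their highest row.

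The implied error of each gene was taken as the authors' natural log fold divided by their statistic and put on the log2 scale. It belongs to the ratio without a pseudocount, covers no biological spread and rests on the authors' model, which gave a few abundant genes errors far from those of their level. From 30 to 100, 100 to 300 and 300 to 1000 FPKM its median stayed at 0.69, 0.68 and 0.69 in culture. In tumours it stayed at 0.30, 0.29 and 0.30. Error from counting alone falls with level, so above 30 FPKM counting cannot be the only part of the implied error. At 1 to 3 FPKM a ratio of 3.86 in culture and 2.95 in tumours lies at the edge of the 95% range of that error at the median gene, and at 100 to 300 FPKM a ratio of 2.53 and 1.49. Relative depth came from genes whose error equals that of 1 fragment in each library. In tumours 94% of these 50 genes lay within 0.05 of their median log2 ratio and in culture 77.5% of 40.

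Protein-coding status came from GENCODE M21 by gene ID, with 11890 of the compared culture genes and 14524 of the tumour genes matched. That annotation is on another build, so none of its coordinates were used. Loci are those of the authors' tables in mm9. Of 19955 loci held by a single gene with a GENCODE length, end minus start equalled the length in 10580 and the length less 1 in 268, so the starts count from 0 and 1 was added. A locus given for more than 1 gene row (4817 compared genes in culture, 5930 in tumours) marks genes that overlap or were assembled together. It is pointed out below for some named genes only, so an unmarked gene may share its locus too.

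Alternatives were pseudocounts of 0.1 and 5, no minimum level, a minimum of 5 FPKM, centring on the median, scaling to the same upper quartile, leaving out repeated symbols, thresholds of 1.5-fold and 3-fold, the authors' call as a further condition, random lists without matching, and Pearson correlation. Protein-coding genes alone, genes with a locus of their own, the authors' call in the overlap and the percentile of the difference between comparisons were added after seeing the data. The code was tested on simulated tables with the real levels and implied errors and 200 changed genes per comparison. Genes without an implied error, such as those listed at 0 in a library, were left out, and errors above 3 were set to 3. The changed genes were drawn from those at 10 FPKM or more. Recovery at lower levels, where the implied error was larger, was not tested. Of 100 genes changed by 1.5 on the log2 scale, 80% in culture and 81% in tumours passed 2-fold in the right direction, and of 100 changed by 3 it was 98% in both. Of 200 random lists, 5.5% and 4.5% fell outside the central 95%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.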

Results

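RNA-seq was used to ask which transcripts differ when mouse Schwann cells without a working Nf2 gene are exposed to NXD30001, named by the series as an inhibitor of the chaperone HSP90. Nf2 encodes merlin, the tumour suppressor lost in neurofibromatosis type 2. The cells were ESC-FC1801, a line of embryonic mouse Schwann cells on an FVB/N background in which floxed Nf2 had been deleted in culture with a Cre adenovirus. There were 4 libraries in 4 groups, 1 in each. Cultured cells had received DMSO or 1 µM NXD30001 for 24 h. Mice with ESC-FC1801 tumours had received vehicle or 100 mg/kg NXD30001 3 times a week for 4 weeks. Levels are FPKM as the authors deposited them, and each difference is treated minus untreated on the log2(FPKM + 1) scale, which understates the change of low genes. With 1 library per group no value has a replicate error, no p-value is given, and "higher" and "lower" describe these libraries only.

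The depth of the libraries is not given by FPKM, but the lowest genes show their relative depth. For 50 genes whose error in the tumour table is that of 1 fragment in each library, the median FPKM ratio was 0.837, so the treated tumour library was 1.19 times as deep as the vehicle library. The same ratio from 40 genes of the culture table gave a treated library 1.05 times as deep. The error implied by the authors' deposited table had a median of 0.69 (SE, log2) for culture genes between 30 and 100 FPKM. For tumour genes of that level it was 0.30. Between 1 and 3 FPKM these medians were 0.99 and 0.80. Single-gene differences in culture thus had more than 2 times the error of those in the tumours at 30 to 100 FPKM.

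Nf2 (ENSMUSG00000009073, chromosome 11 from 4665848 to 4749539, mm9) was listed at 15.9 FPKM with DMSO and 12.5 FPKM with NXD30001 in culture, and at 57.2 and 42.8 FPKM in the vehicle and treated tumours. A whole-gene level does not show whether floxed exons are missing and says nothing on the deletion. The tumours also hold host cells with an intact gene.

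In culture, treated cells held far less RNA of mitosis genes and more of chaperone genes than DMSO cells. All 23 measured members of the G2/M and mitosis list were lower, with a median difference of -4.03, below all 10000 random lists of matched level (percentile 0). Of these, 22 were at least 2-fold lower and 21 were called lower in the authors' deposited table. Mki67, the proliferation marker Ki-67 (ENSMUSG00000031004, chromosome 7 from 142881772 to 142907979), went from 435 to 10.8 FPKM, a difference of -5.21 with an implied error of 0.53. Nusap1, a spindle protein gene, went from 340 to 3.15 FPKM, Aurkb, a mitotic kinase, from 110 to 2.12 FPKM and Ccna2, cyclin A2, from 433 to 13.0 FPKM. The G1/S and DNA replication list was lower as well (21 measured, median -1.70, percentile 0.01). In this list 16 members were at least 2-fold lower and none was 2-fold higher. Tyms, thymidylate synthase, was at 95.7 FPKM with DMSO and 5.76 FPKM with NXD30001, and Gins2, part of the replicative helicase, at 45.6 and 1.02 FPKM.

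The cytosolic heat shock list stood above random lists in culture, with a median of 0.84 (percentile 99.98, 95% of random lists between -0.55 and 0.42). All 20 measured members were higher in treated cells, 7 of them by at least 2-fold. The other listed genes, Hspa1a, Hspa1b, Hspb1 and Hspb8, were not measured in culture, so the list does not show how they responded there. The authors' deposited table called 3 members, Hspa8, Cryab and Hsp90ab1, the last with a difference of 0.45 and an implied error of 0.03. Hspa8, the constitutive HSP70 (ENSMUSG00000015656, chromosome 9 from 40609067 to 40613283, a locus shared with another row), was at 556 FPKM with DMSO and 4453 FPKM with NXD30001, a difference of 3.00 with an implied error of 0.40. The small heat shock protein gene Cryab was at 258 and 1013 FPKM. Hsph1, an HSP110 co-chaperone gene, was at 73.7 and 748 FPKM, but the table's statistic for it implies an error of 133 and no call. The co-chaperone gene Dnajb1 was at 28.7 and 96.1 FPKM, Hspe1 at 57.6 and 208.9 FPKM and Hspa4l at 34.9 and 113 FPKM. Dnaja4 was near the floor at 0.259 and 1.78 FPKM. The other 13 members differed by 0.34 (Hspd1) to 0.96 (Fkbp4). Of the HSP90 genes, Hsp90aa1 was at 1187 and 2117 FPKM, Hsp90ab1 at 2281 and 3111 FPKM, the endoplasmic reticulum form Hsp90b1 at 2560 and 2069 FPKM and the mitochondrial form Trap1 at 19.1 and 8.96 FPKM. The median over these 4 genes was 0.07, and -0.02 in the tumours.

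Protein degradation lists were also higher in treated cells. The proteasome list (26 measured) had a median of 0.63 (percentile 99.9), with Psmb4 at 112 and 494 FPKM and Psmc4 at 16.4 and 56.4 FPKM. Only 1 of its members, Psmb4, was called in the authors' deposited table. The autophagy and lysosome list (22 measured) had a median of 0.68 (percentile 99.98), with 9 members at least 2-fold higher and none 2-fold lower. Map1lc3a and Map1lc3b, which encode LC3 proteins of the autophagosome, were at 5.02 and 77.6 FPKM and at 8.70 and 43.0 FPKM. Sqstm1, the autophagy receptor p62, was at 53.1 and 229 FPKM. The loci of Map1lc3a and Sqstm1 are each shared with another row. The YAP/TEAD target list (16 measured) had a median of 1.19, above all random lists (percentile 100). Its members Cyr61 and Crim1 were at 10.1 and 54.1 FPKM and at 1.90 and 20.5 FPKM. The actin and smooth muscle list (13 measured) had a median of 1.01 (percentile 99.96). Among its examples, Zyx was at 5.64 and 23.1 FPKM and Cnn2 at 12.7 and 41.1 FPKM.

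MAPK output genes, which report signalling through ERK, were lower in treated cells (16 measured, median -1.96, percentile 0). At least a 2-fold lower level was seen for 13 members. The transcription factor genes Etv1 and Etv5 were at 32.9 and 0.208 FPKM and at 21.9 and 0.109 FPKM. Ccnd1, cyclin D1, was at 235 and 29.7 FPKM, and Spry4 was at 8.62 FPKM with DMSO and listed at 0 with NXD30001. The hypoxia and glycolysis list was lower (22 measured, median -1.34, percentile 0, 15 members at least 2-fold lower). In this list Bnip3 was at 265 and 20.04 FPKM and Pdk1, a pyruvate dehydrogenase kinase gene, at 109 and 9.17 FPKM. RNA of the HSP90 client kinases and receptors lay within the range of random lists (15 measured, median -0.41, percentile 29.9), with Axl at 129 and 40.8 FPKM and Pdgfrb at 1.98 and 7.73 FPKM.

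The Schwann cell list divided in culture. Of 21 measured members, 9 were at least 2-fold lower, 5 at least 2-fold higher and 7 within 2-fold, with a median of -0.80 (percentile 1.8). Prx, which encodes the myelin protein periaxin, was at 1.68 and 28.6 FPKM, a difference of 3.47 with an implied error of 0.70. In contrast Egr2, a transcription factor of myelination, was at 12.2 and 0.924 FPKM, and Gap43 was at 20.6 FPKM with DMSO and listed at 0 with NXD30001. This list no longer stood apart from random lists under 5 of the 10 alternatives run for it, with percentiles up to 7.71.

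Single genes with the largest differences in culture, among those the authors' deposited table calls, included proliferation genes and genes of other kinds. Lower in treated cells were Zfp771 (209.2 and 0.271 FPKM), Gemin4 (233 and 1.65 FPKM), Gsta4 (81.8 and 0.101 FPKM), Brip1 (83.0 and 0.203 FPKM), Pold3 (252 and 3.35 FPKM), Cklf (71.9 and 0.365 FPKM) and Hjurp (77.2 and 0.681 FPKM). Brip1 is a DNA repair helicase gene, Pold3 encodes a subunit of DNA polymerase delta and Hjurp a centromere histone chaperone. Tmsb15b2, Gen1 and Mastl were also among the 12 lowest, with differences of -5.34, -5.33 and -5.24. Higher were Ece1 (7.58 and 463.9 FPKM), Tspan7 (3.33 and 168 FPKM), Tcf7l1 (4.24 and 157 FPKM), Sdpr (2.32 and 91.0 FPKM), Arhgef6 (0.397 and 37.2 FPKM), Mrvi1 (0.0123 and 25.6 FPKM), Runx1t1 (0.0523 and 26.0 FPKM), Fbn1 (0.356 and 33.1 FPKM) and Npnt (1.04 and 48.0 FPKM). Fbn1 and Npnt encode extracellular matrix proteins. Coch and Efcab5 differed by 4.39 and 4.31, and Slc24a3 was listed at 0 with DMSO and at 18.9 FPKM with NXD30001. The loci of Ece1, Tspan7, Tcf7l1, Gemin4, Nusap1, Brip1, Mrvi1, Runx1t1, Fbn1, Npnt, Slc24a3 and Efcab5 are each given for another gene row too, and their reads are not assigned with certainty.

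Of 12676 genes compared in culture, 1603 were at least 2-fold higher and 3149 at least 2-fold lower in treated cells. The authors' deposited table called 343 and 894 of these. The median of all compared genes was -0.25, and relative to it 2256 genes were higher and 2331 lower, so the share of lower genes among those changed went from 66.3% to 50.8%. List percentiles compare lists with genes that carry the same shift, and the directions of the lists above held after centring. In simulated tables with only the implied error, 894 unchanged genes passed 2-fold upward and 855 downward among 11330. Genes without an implied error were left out of these tables but are in the counts above.

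**Figure D1:**
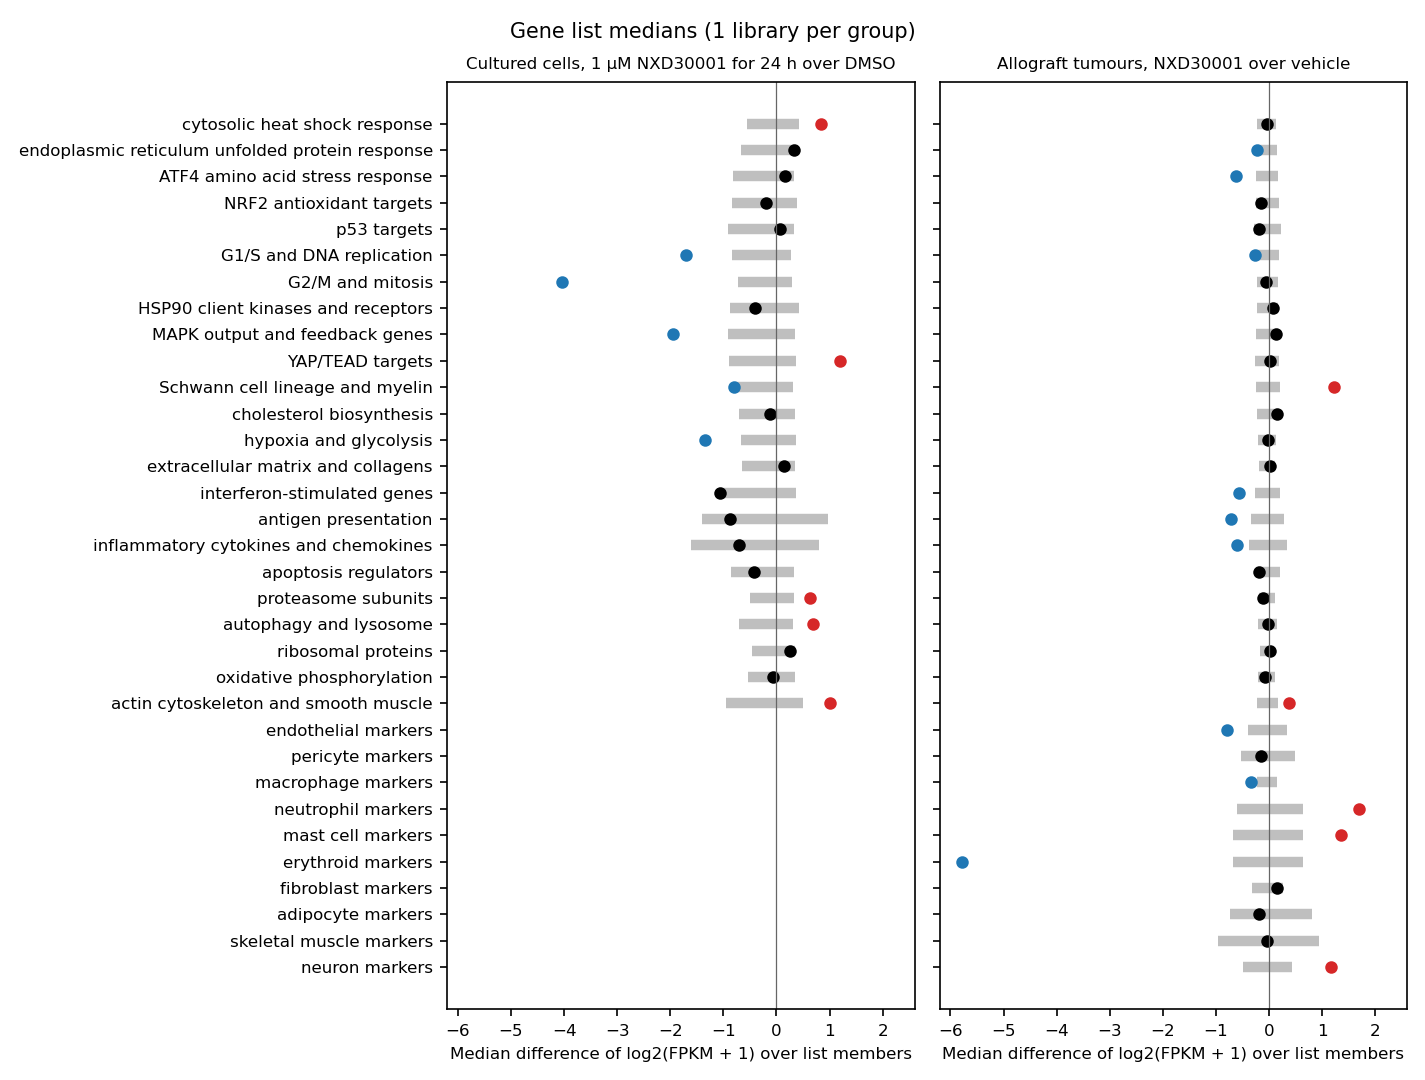
Median difference of log2(FPKM + 1), treated minus untreated, for each gene list with at least 5 measured members in cultured cells (left) and tumours (right), 1 library per group. Points are list medians (red above, blue below, black inside the grey bar) and grey bars span the central 95% of 10000 random lists matched on level. The G2/M list sits at -4.03 in culture and -0.05 in tumours, and the Schwann list at -0.80 and 1.23.

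In tumours, Schwann cell genes were higher in the treated library, while endothelial, antigen presentation and interferon-stimulated genes were lower. The Schwann list (22 measured) had a median of 1.23, above all random lists (percentile 100, 95% of random lists between -0.25 and 0.20). At least a 2-fold higher level was found for 15 members, and none was 2-fold lower. The authors' deposited table called 15 members higher, a set that holds Foxd3 but not Egr2. Foxd3, a neural crest and glial transcription factor gene, was at 24.7 FPKM with vehicle and 116 FPKM with NXD30001, a difference of 2.19 with an implied error of 0.32, and Egr2 at 1.23 and 11.4 FPKM. Markers of other cell types moved beside this list. The neuron list (6 measured) had a median of 1.17 (percentile 99.96), with Nefl and Nefm, which encode neurofilament subunits, at 1.70 and 26.8 FPKM and at 8.49 and 25.7 FPKM. Nefl and Nefm are given the same locus, so their reads are not assigned with certainty, and 4 of the 6 members share a locus with another row.

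Endothelial markers were lower in the treated tumour (16 measured, median -0.79, percentile 0.02), with 15 of the 16 below 0 and 6 at least 2-fold lower. Cdh5, VE-cadherin, was at 17.9 and 5.84 FPKM, a difference of -1.47 with an implied error of 0.36. Tek, an angiopoietin receptor gene, was at 6.30 and 0.864 FPKM, Sox18 at 8.67 and 2.19 FPKM and Emcn at 8.86 and 2.85 FPKM. Globin RNA was nearly missing from the treated library. Hba-a1 and Hba-a2 were at 110.0 and 104 FPKM with vehicle and listed at 0 with NXD30001, and Hbb-b2 and Hbb-b1 were at 65.9 and 0.213 FPKM and at 33.8 and 0.164 FPKM. The members of each globin pair are near-identical copies, so levels of the single genes are uncertain. These 4 globins were the lower members of the erythroid list (5 measured, median -5.79, percentile 0). Its remaining member, Alas2, a haem synthesis gene chosen here after its values were seen, was higher (0.610 and 4.72 FPKM, a difference of 1.83 with an implied error of 2.90 and no call), at a locus shared with another row.

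Immune lists moved in both directions between the tumours. The interferon-stimulated list (24 measured) had a median of -0.56 (percentile 0), with Oasl1 at 17.8 and 2.90 FPKM and Mx1 at 5.48 and 1.94 FPKM. The antigen presentation list (14 measured) had a median of -0.71 (percentile 0.01). Its members Cd74, H2-Eb1 and H2-Aa, which belong to MHC class II presentation, were at 31.3 and 4.65 FPKM, at 10.97 and 0.734 FPKM and at 7.24 and 0.735 FPKM. The cytokine and chemokine list (15 measured) had a median of -0.60 (percentile 0.16), with the chemokine gene Ccl5 at 20.4 and 0.884 FPKM. It no longer stood apart without the genes that share a locus (median -0.15, percentile 22.1) or without the minimum level (median -0.23, percentile 4.72). All 20 macrophage markers were lower, with a median of -0.33 (percentile 0.19) and 2 of them at least 2-fold lower, namely Ms4a7 at 52.7 and 18.6 FPKM and Mrc1 at 60.7 and 24.3 FPKM. Mast cell markers were higher (8 measured, median 1.36, percentile 99.97), with Hdc, histidine decarboxylase, at 0.554 and 10.9 FPKM and Tpsab1 at 4.10 and 19.6 FPKM. Neutrophil markers had a median of 1.70 (percentile 99.97) over 5 members, of which 3 were higher and 2 lower. The higher were S100a8 at 2.18 and 21.9 FPKM, S100a9 at 6.96 and 24.8 FPKM and Retnlg at 0.539 and 4.06 FPKM, none of them called in the authors' deposited table. The only called member, Mmp9, which was also the most abundant with vehicle, was lower at 90.2 and 45.8 FPKM.

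Stress lists differed between the tumours in another way than in culture, where exposure lasted 24 h; the time from the last dose to tumour collection is not given in the sources used here. The cytosolic heat shock list lay in the middle of random lists (24 measured, median -0.05, percentile 47.7), with Hspa8 at 1392 and 1381 FPKM, Hsp90aa1 at 672 and 667 FPKM and Hsp90ab1 at 1497 and 1460 FPKM. Of its members 22 were within 2-fold, Hsph1 was at 137 and 67.7 FPKM and Cryab at 157 and 370 FPKM. The ATF4 list, genes of amino acid synthesis and transport under stress, was lower (19 measured, median -0.63, percentile 0). Psph, of serine synthesis, was at 113 and 37.6 FPKM and Pck2 at 43.9 and 16.1 FPKM. The unfolded protein response list had a median of -0.23 (19 measured, percentile 1.72), with Hspa5, the chaperone BiP, at 1376 and 790 FPKM, an implied error of 0.17 on a difference of -0.80, and Hsp90b1 at 774 and 520 FPKM. Trap1 was at 77.9 and 79.98 FPKM. The G2/M list did not stand apart (24 measured, median -0.05, percentile 41.8), and the G1/S list had a small median of -0.27 (22 measured, percentile 1.09) with no member 2-fold changed. The unfolded protein response and G1/S lists crossed back inside the random range under 2 and 1 of the 10 alternatives. The actin and smooth muscle list was higher, as it was in culture (13 measured, median 0.37, percentile 99.92), with Acta2 at 82.0 and 186 FPKM and Flna at 1447 and 2165 FPKM.

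The extracellular matrix list did not stand apart (26 measured, median 0.03, percentile 77.5), with members moving in both directions. No member was 2-fold higher and 4 were at least 2-fold lower, namely Bgn (1693 and 487 FPKM), Col12a1 (102 and 36.3 FPKM), Fn1 (1596 and 660 FPKM) and Fbn1 (48.1 and 22.4 FPKM). The authors' deposited table called 7 members lower and 4 higher, the latter, named here after their values were seen, being Tnc (0.81), Col4a1 (0.53), Lamb1-1 (0.29) and Nid1 (0.13). The implied errors of Col4a1, Lamb1-1 and Nid1 were only 0.05, 0.03 and 0.03, and that of the lower member Fn1 was 0.01. These lie far below the tumour median of 0.29 between 100 and 300 FPKM, so calls of small differences rest on unusually small errors. Among HSP90 clients (21 measured, median 0.08, percentile 86.5), Egfr was at 42.3 and 18.8 FPKM, Pdgfrb at 20.9 and 45.9 FPKM and Erbb3, a neuregulin receptor gene, at 12.4 and 26.3 FPKM. In the hypoxia list (24 measured, median -0.02, percentile 59.4), Car9, carbonic anhydrase IX, was at 37.0 and 8.60 FPKM and Aldoc at 15.6 and 2.90 FPKM.

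Among genes higher in the treated tumour that the authors' deposited table calls, the largest difference was that of Saa3, an acute phase protein gene, at 2.42 and 129 FPKM. Also higher were Rtf1 (21.3 and 782 FPKM), Zfr2 (1.37 and 37.9 FPKM), Nmb (0.813 and 24.1 FPKM), Ribc1 (0.448 and 18.4 FPKM), Chka (1.56 and 33.0 FPKM), Pcdh10 (0.878 and 21.5 FPKM) and the small heat shock protein gene Hspb7 (0.784 and 19.5 FPKM). Ccdc30 and the chemokine gene Cxcl13 were listed at 0 with vehicle and at 17.2 and 10.4 FPKM with NXD30001. Lower, besides the globins and Ccl5, were Lypd6 (11.4 and 0.191 FPKM), Zdhhc12 (11.5 and 0.501 FPKM), the RNA sensor gene Tlr7 (29.99 and 2.92 FPKM), Anpep (39.8 and 4.26 FPKM), the keratin gene Krt18 (17.4 and 1.39 FPKM), the proteoglycan gene Acan (31.9 and 3.50 FPKM) and Tnfrsf26 (8.71 and 0.337 FPKM). Ccdc30, Nmb, Chka and Zdhhc12 have loci that are given for another row too.

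Of 15550 genes compared in tumours, 1139 were at least 2-fold higher and 1077 at least 2-fold lower, with a median of all genes of -0.03. The authors' deposited table called 387 and 298 of these. The implied error alone gave 371 and 349 such genes among 14414 unchanged genes in simulated tables. Genes without an implied error were left out of the simulated tables but are in the counts of changed genes.

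**Figure D2:**
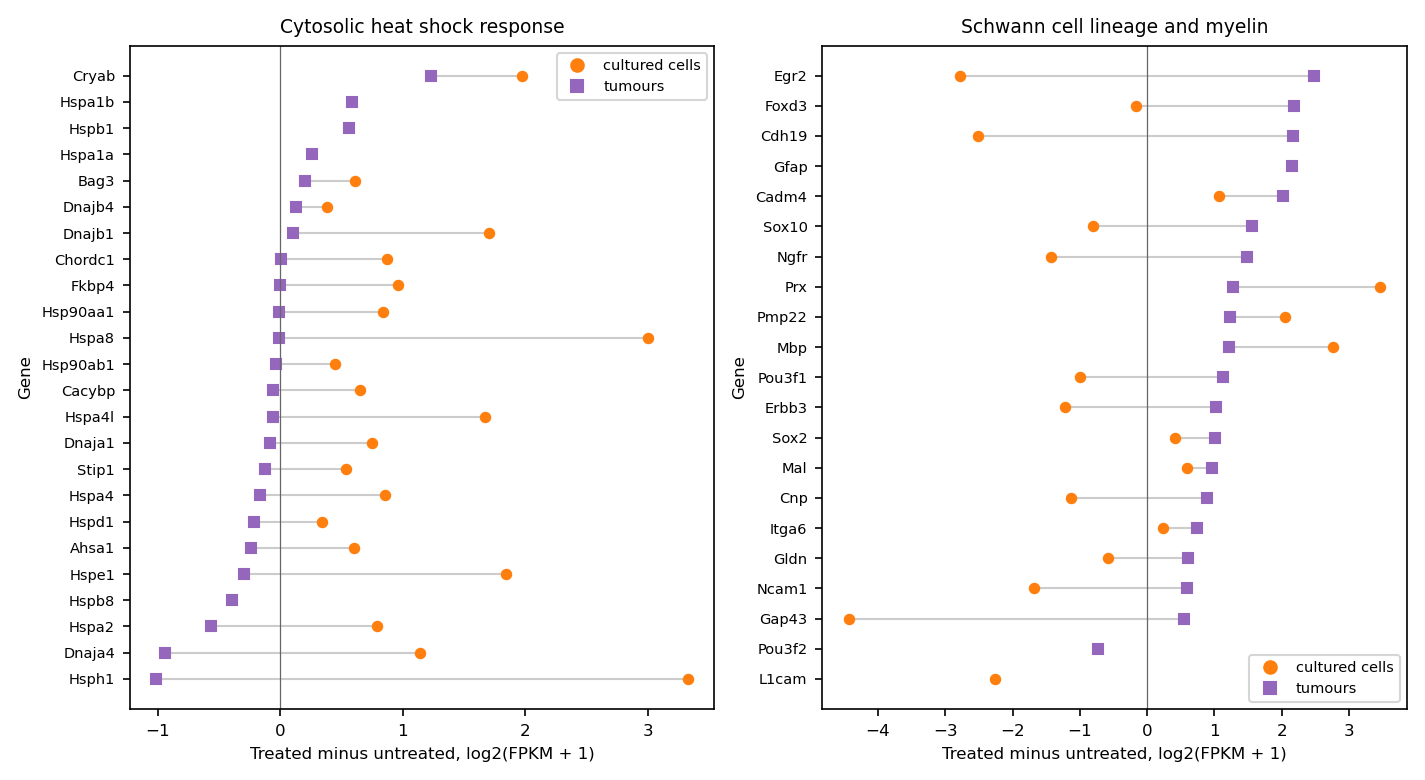
Difference of log2(FPKM + 1), treated minus untreated, for each measured member of the heat shock list (left) and the members of the Schwann list reported here (right), in cultured cells (orange circles) and tumours (purple squares), 1 library per group, with grey lines joining a gene measured in both. All 20 heat shock members measured in culture lie above 0, and all Schwann members drawn for tumours except 1 do.

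Across the 11559 genes compared in both tables, the culture and tumour differences were nearly unrelated (Spearman correlation across genes 0.01, where genes are not independent replicates). Error of the size implied, with a median of 0.69 in culture and 0.30 in tumours between 30 and 100 FPKM, weakens such a correlation. The value therefore does not show that the responses themselves are unrelated. In both, 117 genes were at least 2-fold higher and 176 at least 2-fold lower, where independent lists would share 66.9 and 108. The opposite directions held 82 genes (higher in culture, lower in tumours) and 193 genes (lower in culture, higher in tumours), against 53.8 and 134. In all, 293 genes went the same way and 275 opposite ways. The numbers for independent lists were not matched on level. Higher in both were Prss12 (2.10 and 22.8 FPKM in culture, 1.14 and 11.6 FPKM in tumours), the sodium channel gene Scn7a (1.72 and 13.2 FPKM, 14.1 and 76.7 FPKM), Cadm2 and Npnt. Lower in both were Pold3 (102 and 16.9 FPKM in tumours), Hdhd3, Kctd13 and Adam12. Opposite were Egr2, Nmb, the cadherin gene Cdh19 (10.6 and 1.04 FPKM in culture, 4.91 and 25.7 FPKM in tumours), Itih5 (272 and 58.2 FPKM, 38.6 and 149 FPKM), Grik2 (73.1 and 15.3 FPKM, 0.210 and 3.55 FPKM) and Col28a1, all lower in culture and higher in tumours. Rasgef1c and the histone gene Hist1h4k, whose near-identical copies make its level uncertain, had the same pattern. Mtus1 (2.81 and 16.4 FPKM, 40.2 and 8.02 FPKM) and Peli3 went the other way. Of these shared and opposite genes, Kctd13 and Hist1h4k were called in neither of the authors' deposited tables. Cadm2, Egr2, Col28a1 and Peli3 were called only in culture, and Hdhd3, Adam12 and Nmb only in tumours. The others named were called in both. The loci of Cadm2, Npnt, Kctd13, Adam12, Nmb and Mtus1 are each given for another row too. The tumour difference of Egr2 was smaller than its implied error, so its direction there is uncertain.

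The difference of the comparisons was itself set against random lists, gene by gene within each list. It stood apart for the heat shock (20 members in both, median tumour minus culture difference -0.85, percentile 0.16), ATF4 (-0.84, 0.02), YAP/TEAD (-1.12, 0.01), proteasome (-0.78, 0.11) and autophagy lists (-0.65, 0.25), each relatively higher in culture. It stood apart the other way for the G2/M (4.08, 100), G1/S (1.29, 99.93), MAPK (2.29, 100), hypoxia (1.52, 100) and Schwann lists (2.08, 100). For the unfolded protein response (-0.53, 2.63) and actin lists (-0.67, 3.19) it did not.

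**Figure D3:**
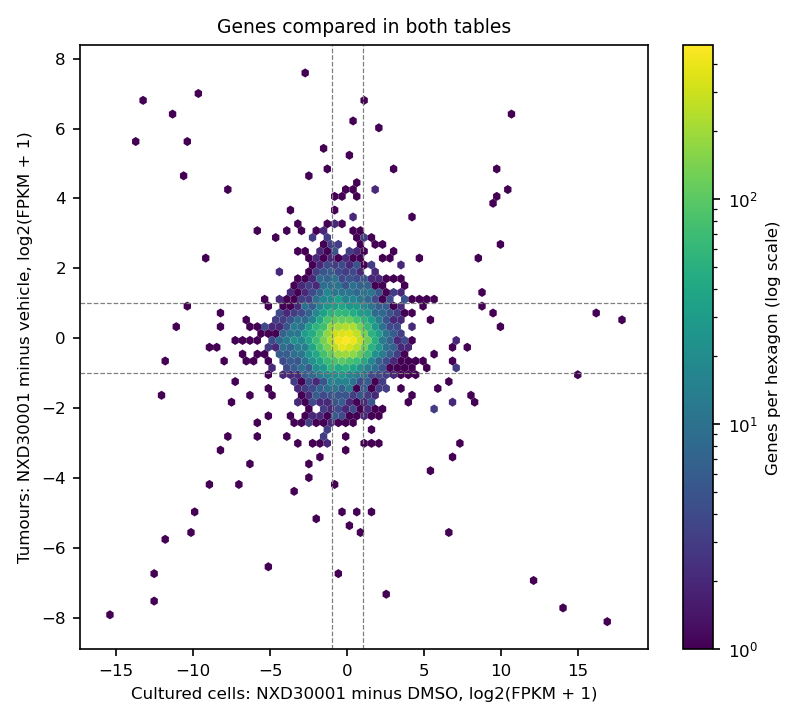
Difference of log2(FPKM + 1) in cultured cells (x axis) against that in tumours (y axis) for the 11559 genes compared in both tables, as the number of genes per hexagon on a log colour scale, with dashed lines at 2-fold. The cloud is wider along the culture axis and shows no slope, with a Spearman correlation of 0.01.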

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

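The tests of host cell dilution and of neuron RNA were chosen after their results were seen, and the test of spread within the list before.

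The median of the Schwann cell lineage and myelin list was -0.80 in culture and 1.23 in tumours. The list divided in culture, with 9 members at least 2-fold lower and 5 at least 2-fold higher. It stood apart there under 5 of the 10 alternatives. Prx, Mbp and Pmp22, picked after their values were seen, were higher and called in both comparisons. Their deposited log2 folds were 4.09, 2.86 and 2.05 in culture and 1.53, 1.25 and 1.24 in tumours. Others, such as Cdh19, were lower in culture and higher in tumours. Over the 20 members measured in both, the tumour difference exceeded the culture difference by a median of 2.08, and by more than 0 in 17 of them. With 1 library per group the difference was not tested against replicate error.

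A larger share of grafted cells in the treated tumour piece could raise all Schwann genes at once. If all host cell types had been diluted alike, their marker lists would have fallen together, but the mast cell median exceeded the macrophage median by 1.69, where 95% of the differences between random lists of those sizes lay between -0.67 and 0.72, which argues against that form as the whole cause. The mast cell median itself ranged from 0.63 to 1.95 over the alternatives, and its difference from the macrophage median lay outside the random range under each that gave a value (0.95 with a pseudocount of 5, 1.62 without the minimum). The mast cell members with the largest differences were low with vehicle, however (Hdc 0.554, Cma1 0.898, Tpsb2 3.13 and Tpsab1 4.10 FPKM). Hdc and Cma1 passed the 1 FPKM minimum only in the treated library. A 5 FPKM minimum left too few members for a value, so the argument rests on low genes and is limited. A share that changed together with the host makeup stays open, since the spread of the members (SD 1.05) lay inside the 0.40 to 2.69 of random lists, a range too wide to decide. More neuron RNA in the treated piece also stays open, because the neuron list was higher (median 1.17), yet 2 of its 3 members above 10 FPKM with vehicle were lower and 4 of its 6 members share a locus with another row. A response of the grafted cells to 4 weeks of NXD30001, the difference the design names, stays among the open explanations as untested.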

How the results depend on the processing

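The tests on protein-coding genes, on genes with a locus of their own and with the authors' call in the overlap, and those of the differences between marker lists under other settings, were chosen after seeing the data. Of the 10 lists that stood apart in culture, 9 did so under every alternative run, and 11 of the 14 in tumours. The Schwann list in culture moved inside the random range with a pseudocount of 5 (median -0.44), no minimum (-0.57), a 5 FPKM minimum (-0.80), protein-coding genes (-0.69) and unmatched random lists (-0.80). In tumours the unfolded protein response list did so with own loci (-0.23) and unmatched lists (-0.23), the G1/S list with own loci (-0.27) and the cytokine list with no minimum (-0.23) and own loci (-0.15). In culture the unfolded protein response list moved above the range with own loci (0.58), and the interferon-stimulated list below it with protein-coding genes, own loci and unmatched lists (-1.06 in each). The cause was not tested. Alternatives that left a list fewer than 5 members gave no value. The heat shock median ranged from 0.77 to 1.10 in culture and from -0.06 to -0.02 in tumours, the G2/M median from -4.37 to -3.14 in culture and the Schwann median from 1.01 to 1.52 in tumours. Other medians moved further. In culture the YAP/TEAD median ranged from 0.59 to 1.44, the actin median from 0.58 to 1.36 and the G1/S median from -1.96 to -1.13. In tumours the neutrophil median ranged from 0.58 (no minimum) to 1.82 (pseudocount 0.1), the mast cell median from 0.63 (pseudocount 5) to 1.95 (pseudocount 0.1), the endothelial median from -1.18 (5 FPKM minimum) to -0.43 (pseudocount 5), the erythroid median from -7.72 to -3.77, the antigen presentation median from -0.86 to -0.44 and the cytokine median from -0.81 to -0.15. With a pseudocount of 5 the mast cell median still exceeded the macrophage median by more than random lists (0.95, 95% of random lists between -0.31 and 0.37), while the endothelial median no longer lay apart from it (-0.10, between -0.25 and 0.28). The endothelial median lay below the macrophage median by more than random lists under the other 9 alternatives (-0.79 with a pseudocount of 0.1, -0.85 with a 5 FPKM minimum). The correlation of the comparisons lay between 0.00211 (protein-coding genes) and 0.0189 (Pearson). Of 348 named gene results under other pseudocounts and scalings, 68 values moved beyond the 95% range of the implied error (1.5-fold where none is given), 1324 did not, and none past 2-fold changed sign.

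Counts moved more. Genes higher and lower in culture numbered 908 and 1694 with a pseudocount of 5, 2758 and 4769 at 1.5-fold, 703 and 1601 at 3-fold, 343 and 894 with the authors' call too, and 954 and 1865 with a locus of their own. In tumours they numbered 451 and 424, 2213 and 2302, 488 and 456, 387 and 298, and 555 and 532 under the same settings, 734 and 675 with a 5 FPKM minimum and 658 and 584 among protein-coding genes. Fewer genes enter under the last 2 kinds and under loci of their own, which lowers counts by construction. A larger pseudocount shrinks every difference, so it lowers the counts by construction as well. Genes shared as higher in both, lower in both, higher in culture but lower in tumours, and the reverse numbered 40, 49, 29 and 53 with a pseudocount of 5, 75, 104, 46 and 106 with a 5 FPKM minimum, 76, 96, 39 and 121 among protein-coding genes, 325, 593, 274 and 550 at 1.5-fold, and 26, 15, 12 and 30 with the authors' call too, where independent lists would share 6.63, 10.7, 3.80 and 18.7. At 1.5-fold independent lists would share 267, 466, 271 and 460, so the excess of genes higher in culture but lower in tumours was nearly gone. With a pseudocount of 0.1, 274 were lower in both and 290 lower in culture but higher in tumours. The median implied error in culture was 0.99 between 1 and 3 FPKM and 0.69 between 30 and 100 FPKM.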

Other observations

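Lists not described above mostly lay within the random range. In culture these were the unfolded protein response (median 0.33, percentile 95.7), ATF4 (0.16, 91.1), NRF2 (-0.20, 52.7), p53 (0.06, 86.8), cholesterol (-0.11, 59.2), extracellular matrix (0.14, 86.3), interferon-stimulated (-1.06, 2.75), antigen presentation (-0.88, 18.7), cytokine (-0.71, 24.9), apoptosis (-0.42, 29.7), ribosomal (0.25, 93.4) and oxidative phosphorylation lists (-0.07, 53.4). Centring turned the sign of the NRF2 (0.05), cholesterol (0.14) and oxidative phosphorylation medians (0.18). Other alternatives turned that of the extracellular matrix median (range -0.34 to 0.39) and the p53 median (range -0.08 to 0.31). Within them Hspa5 was at 316 FPKM with DMSO and 1004 FPKM with NXD30001, the ubiquitin ligase gene Syvn1 at 1.88 and 20.8 FPKM, the stress factor gene Atf3 at 2.80 and 20.98 FPKM, Gadd45a at 5.73 and 72.2 FPKM, Ftl1, ferritin light chain, at 48.1 and 232 FPKM and the matrix gene Postn at 27.8 and 0.941 FPKM. In tumours they were the NRF2 (-0.15, 13.8), p53 (-0.19, 10.3), MAPK (0.13, 92.9), YAP/TEAD (0.02, 69.4), cholesterol (0.15, 96.1), apoptosis (-0.19, 7.47), proteasome (-0.11, 17.1), autophagy (-0.01, 56.0), ribosomal (0.02, 76.0), oxidative phosphorylation (-0.07, 32.9), pericyte (-0.15, 30.8), fibroblast (0.15, 88.8), adipocyte (-0.18, 28.2) and skeletal muscle lists (-0.03, 50.3). Their members Fabp4, a lipid-binding protein gene, at 65.8 and 12.5 FPKM and Bid at 14.2 and 32.4 FPKM were called in the authors' deposited table. Fewer than 5 members were measured of the T and NK cell list in tumours (2, median -0.73), the keratinocyte list (2, 0.48) and, in culture, the endothelial (2, 0.20), pericyte (2, 1.11), macrophage (1, -0.18), fibroblast (4, -1.19), skeletal muscle (3, -0.41), keratinocyte (2, 1.14) and neuron lists (1, 0.00). None of the neutrophil, T and NK, B, mast, erythroid or adipocyte markers was measured in culture, and none of the B cell markers in tumours.

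Genes were also grouped by symbol stem, a grouping chosen after the fixed lists were seen, with its test set before it was run. Of 134 stems with 8 or more genes in both tables, 15 stood apart in culture and 9 in tumours, where chance puts 6.7 outside in each, and 2 did in both, where chance puts 0.335. These chance numbers treat the genes of a stem as independent. Histone genes (stem Hist, 36 genes, many of them near-identical copies) were lower in culture (median -1.22) and higher in tumours (0.39), and nucleoporin genes (stem Nup, 18 genes) were lower in both (-1.03 and -0.25). Among the others, picked after their values were seen, kinesin (Kif, 24 genes, -1.48) and Mcm genes (9 genes, -1.68) stood below random lists in culture, and Rab (48 genes, 0.25) and Sec genes (23 genes, 0.57) above. In tumours these 4 stems lay inside the random range (0.11, -0.27, -0.14 and -0.16, percentiles 91.9, 6.78, 4.75 and 11.2), and the difference between the comparisons was not tested for stems. The 2 stems shared by both comparisons are too few to tell from chance.

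Among the tests of the culture and globin patterns that follow, those of a single scaling factor, of moved globin reads, of all host cell types falling alike and of blood, and the repeats under other settings, were chosen after their results were seen.

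More genes were lower than higher in treated culture. Centring gave 2256 higher and 2331 lower genes. It brings the 2 counts near balance whatever the cause, so it does not single out a scaling factor. Scaling to the same upper quartile gave 2054 and 2580. Over 5 bins of mean level, the median went from -0.51 in the lowest to -0.03 in the highest, a difference of 0.48 (bootstrap 95% interval 0.39 to 0.55). A single scaling factor would shift all bins alike, or the low ones less, since a pseudocount damps the shift of low genes. It does not account for this trend, though it may account for part of the excess of lower genes. Reads divided between genes of 1 locus do not account for that excess, since 66.2% of the changed genes with a locus of their own were lower. Counting error at low levels would leave the 2 directions near even at 30 FPKM or more. There 60.8% were lower, with a Wilson 95% interval of 58.5% to 63.1% (treating genes as independent), and 53.9% after centring. The interval includes the 60% set as the bound but lies away from an even split, and centring brings the share nearer to one. Simulated error, symmetric by construction, gave 894 unchanged genes higher and 855 lower, which cannot bear on the direction. The test therefore does not decide on counting error at low levels, which stays open. A shift that depends on level, technical or from the treatment, stays open too.

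Globin and endothelial RNA was lower in the treated tumour. Reads moved between near-identical globin copies cannot account for it, since the sum of the 4 genes was 831 times as high with vehicle (314 and 0.378 FPKM). A fall of all host cell types alike is argued against by the mast cell median, 1.69 above that of the macrophages. That argument is limited, since the mast cell members with the largest differences were low with vehicle (Hdc 0.554, Cma1 0.898, Tpsb2 3.13 and Tpsab1 4.10 FPKM). A 5 FPKM minimum left too few mast cell members for a value. The endothelial median lay -0.46 from the macrophage median, outside the -0.40 to 0.42 of 95% of random lists of those sizes, which argues against a like fall of these 2 cell types. It lay outside under 9 of the 10 alternatives (-0.79 with a pseudocount of 0.1, -0.85 with a 5 FPKM minimum) and inside with a pseudocount of 5 (-0.10, between -0.25 and 0.28), so this argument depends on the pseudocount. Less blood in the treated piece may lower the globins. The neutrophil median of 1.70 goes against it, but was 0.58 without the minimum level and rests on 5 members of which 1 was above 10 FPKM with vehicle, so it cannot be told apart from fewer vessels or from how the piece was sampled. An effect of the treatment on vessels stays open and untested.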
